A study of Mus musculus with 16 samples.

How the data were processed

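Bulk RNA sequencing measured the transcripts of E14 mouse embryonic stem cells (line ES-E14TG2a) of 2 genotypes, written WT and TKO in the labels, on days 0, 2, 4 and 7 of differentiation toward epiblast-like cells. Each of the 8 groups held 2 libraries that the labels call biological replicates, 16 libraries in all. The labels do not expand TKO; it was assumed to stand for loss of the DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b, and the levels of these genes were examined in every library. Libraries were made with a stranded messenger RNA protocol, per the labels.

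The deposited tables hold, per transcript and library, estimated counts (expected counts from kallisto), which are not normalised for depth or length, per the file headers. The deposited tables also hold TPM, scaled for depth and length, which summed to the same total in every library, and an effective length in bases, a column of other kind, per the file headers. Per the submitters' processing notes the tool was kallisto, without a version, and the genome builds named were GRCm38 and mm10; the transcript annotation and its release are not stated there. Estimated counts were used for every result, effective lengths for 1 alternative, and TPM for no result.

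Each table listed 119414 transcripts, of which 116728 (97.8%) matched a transcript of the GENCODE annotation vM21 for GRCm38 by identifier. Their estimated counts were summed per gene and rounded to whole numbers, which gave 35975 genes, among them 21897 protein-coding genes and 13518 pseudogenes. Unmatched transcripts held between 0.95% and 1.05% of the counts of a library. H19, Meg3, Rian, Mirg, Kcnq1ot1, Airn, Peg13 and Dub1, which were on the fixed lists, were not analysed here. Total estimated counts ran from 33168178 to 58197630 per library; intervals and floors given for low counts cover counting error only.

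Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood fit with robust dispersions) on all 16 libraries, with 1 mean per group, so that the groups shared 8 residual degrees of freedom. The filter kept 18489 genes, 17004 of them protein-coding, and the common biological coefficient of variation was 0.111. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes are the fold change over the square root of the test statistic. Values per group are CPM (counts scaled by effective library size) with the standard deviation over 2 libraries. The comparisons were TKO against WT on each day, each later day against day 0 within each genotype, and the change of the TKO against WT difference from day 0 to each later day (the interaction). The replicate number was not used as a block, because the labels do not say that it marks a shared day; with a replicate block the counts are those given in the closing section. Genes with 0 counts in both libraries of a group are given as bounds against a floor of 3 counts over the group, and genes with 1 to 3 counts as a ratio with a 95% exact binomial interval.

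Gene lists were tested with limma 3.58.1 by camera with an inter-gene correlation preset at 0.01, which asks whether the genes of a list moved more than other genes. The family held 120 tests, 20 lists in 6 comparisons, adjusted together by Benjamini-Hochberg. Camera was repeated with a correlation estimated from the data, and fry was run beside it; fry asks whether the genes of a list moved on balance in one direction, or, in its mixed form, whether they moved in either, without comparing them with other genes. The lists covered the DNA methylation machinery, naive, core, and formative and primed pluripotency, germline genes, primordial germ cell factors, X-linked Rhox, Xlr and Mage genes, two-cell-stage genes, neural, primitive streak and mesoderm, endoderm, trophoblast, and feeder and stromal fibroblast markers, imprinted genes, interferon response, p53 targets, FGF-ERK targets, Nodal-Activin targets, beta protocadherins and Hox genes. Some lists held genes with several near-identical copies (Zscan4, Usp17l, Rhox, Xlr, Tuba3 and Pramel families); reads shared among copies make the level of a single member uncertain.

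The lists, comparisons, tests, thresholds, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names, for each comparison of genotypes, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l and Uhrf1, the 8 largest rises and the 8 largest falls among called protein-coding genes with at least 5 CPM in the higher group and both libraries of one genotype above both of the other (predicted genes left out), up to 2 called members per direction of each list with the lowest adjusted p, and a fixed set of markers. A list without a called member is represented by the 2 members with the highest mean. For day 7 against day 0 the 6 largest rises and falls were taken, and for interactions the 5 largest in each direction. Some of these genes are left out of the text, and a few are not reported here.

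The chain of steps was tested on simulated data, counts with known changes in 200 genes. At day 0, 38% of genes changed 1.5-fold, 70% of those changed 2-fold and 96% of those changed 4-fold were recovered, with 6 false calls among 17725 genes. At day 7 the shares were 56%, 86% and 96%. The simulation gave every group the same spread per gene. In the data the replicates of WT day 0 differed far more than those of TKO day 0 (chi-square per degree of freedom 66.7 and 1.81). The shares and the false calls therefore do not cover unequal spread between groups. Chromosome medians of log2 fold changes were compared with those of 10000 random gene sets matched on expression. The alternatives were another scaling (RLE), no filter and a stricter filter on low counts, a stricter threshold, a replicate block, an offset for effective length, fits on only the libraries compared, DESeq2 1.42.0, and leaving out each library in turn. In the last, the lone library of a group was assumed to vary like the other groups. Counts without the genes of proximal chromosome 6, and a pair of further block designs, were added after the data were seen.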

Results

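The data were 16 libraries of bulk RNA from mouse embryonic stem cells of the line E14, wild type (WT) or TKO, 2 biological replicates per group. Day 0 cells grew with LIF, inhibitors of Gsk3 and MEK and vitamin C, a medium that holds them in the naive state of the preimplantation epiblast. Days 2, 4 and 7 followed a switch to Fgf2 and Activin A, which drives them toward epiblast-like cells, with an extra split at day 4. Total estimated counts ran from 39799498 to 58197630 in the 8 WT libraries and from 33168178 to 47064338 in the 8 TKO libraries. Positions are on GRCm38, and ± is the SD over 2 libraries for CPM and the SE for log2 fold changes.

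The first principal component of the 2000 most variable genes held 58.8% of their variance and the second 17.4%. Replicates correlated at 0.987 or above across genes (Pearson, log2 CPM, genes being no independent replicates). TKO day 4 had the most genes far apart between its libraries: 166 genes at 5 CPM or more differed over 2-fold, 77 higher and 89 lower in replicate 1. WT day 0 followed with 116 and WT day 4 with 80, while the other groups had 14 or fewer. By the median absolute log2 difference WT day 0 was the widest group (0.241 against 0.140 in TKO day 4), as it was by chi-square per degree of freedom (66.7 against 28.6). Across the genome the median log2 fold change of TKO against WT lay between -0.02 and 0.01 on the 4 days.

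**Figure D1:**
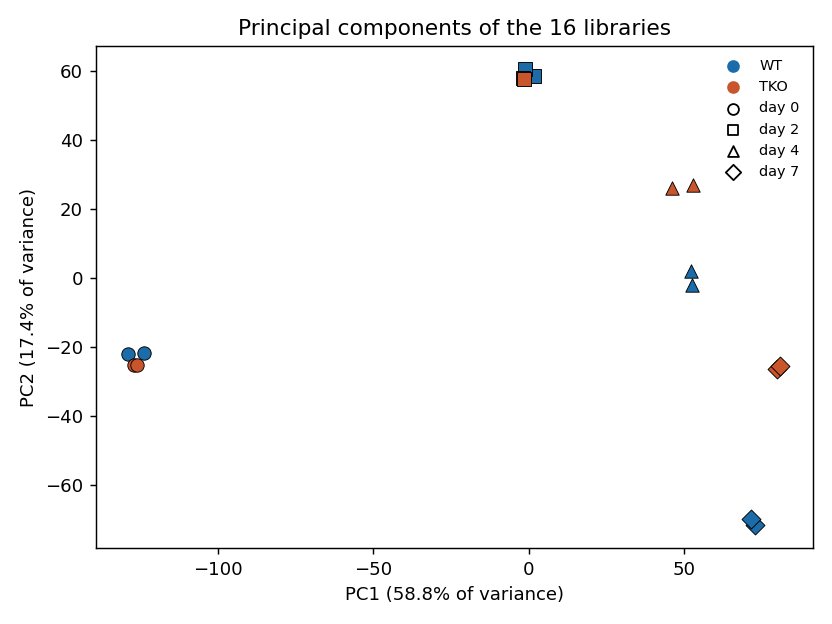
Principal components of the 16 libraries over the 2000 most variable genes (log2 CPM), with component 1 (58.8% of variance) on the x axis and component 2 (17.4%) on the y axis; each point is 1 library, colour gives the genotype and the marker the day.

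The labels do not expand TKO; that it stands for loss of Dnmt1, Dnmt3a and Dnmt3b is an assumption here. Of these genes Dnmt1 transcripts were reduced on each day, Dnmt3a on days 0, 2 and 7, and Dnmt3b from day 2. Dnmt1 (ENSMUSG00000004099.16, chromosome 9, 20907209 to 20959888), the maintenance methyltransferase, stood at 55.2 ± 1.05 CPM in TKO and 501 ± 61.9 in WT at day 0. Its log2 fold changes were -3.18 ± 0.10, -3.07 ± 0.10, -3.04 ± 0.10 and -3.08 ± 0.10 on days 0, 2, 4 and 7, with a highest adjusted p of 1.62e-09 (edgeR, Benjamini-Hochberg). Dnmt3a (ENSMUSG00000020661.15, chromosome 12, 3806007 to 3914443), a de novo methyltransferase, changed by -3.53 ± 0.71 at day 0 (adjusted p = 0.0117), -4.08 ± 0.61 at day 2 (0.00319) and -3.13 ± 0.60 at day 7 (0.00209). Its SE rests on the spread in all 8 groups, among them TKO day 4, whose libraries read 187 and 33.9 CPM. At day 0 Dnmt3a read 2.79 and 2.45 CPM in the TKO libraries and 27.5 and 33.1 in the WT libraries. At day 0 its call was lost with an effective-length offset (0.0529), without WT replicate 1 (0.0572) and without TKO replicate 1 (0.0861) or 2 (0.0937). Dnmt3b (ENSMUSG00000027478.15, chromosome 2, 153649450 to 153687730), the other de novo enzyme, was at 29.1 ± 0.260 CPM in TKO and 28.3 ± 1.41 in WT at day 0, a difference not detected (0.04 ± 0.20, adjusted p = 0.941). It was lower in TKO by -0.91 ± 0.19 at day 2 (0.00845), -1.22 ± 0.19 at day 4 (0.000444) and -1.71 ± 0.19 at day 7 (1.39e-05). The day 2 call was lost without TKO replicate 2 (0.0867). A deleted exon can leave a measurable transcript, so these levels neither measure protein nor establish the genotype.

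At day 4 the TKO replicates differed in Dnmt3a, with 187 CPM in replicate 1 and 33.9 in replicate 2, against 297 and 380 in WT. The difference of -1.61 ± 0.56 was not called (adjusted p = 0.0552); without TKO replicate 1 it was -3.33 (8.63e-08) and without replicate 2 it was -0.86 (0.000766). Dnmt1 was alike in both, at 36.2 and 40.7 CPM. Dnmt3b differed as well, at 431 CPM in replicate 1 and 757 in replicate 2, as did Dnmt3l, at 42.2 and 17.4. Dnmt3l, the cofactor of the de novo enzymes, was higher in TKO at day 4 (3.77 ± 0.36, adjusted p = 2.35e-05) and at day 7 (2.37 ± 0.59, 0.00712). Uhrf1, which recruits Dnmt1, was not called at day 0 (0.06 ± 0.07, 0.633) or day 2 (0.14 ± 0.07, 0.224) and was slightly higher in TKO at day 4 (0.25 ± 0.07, 0.0206) and day 7 (0.29 ± 0.07, 0.00558). The day 4 call was lost without WT replicate 1 (0.108) or 2 (0.0530), without TKO replicate 1 (0.109), with no filter on low counts (0.0529) and with only the libraries compared (0.0542). The day 7 call was lost without WT replicate 1 (0.0640) or 2 (0.0651) and without TKO replicate 1 (0.106).

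The DNA methylation machinery list was called lower at day 2, with 1 member higher and 4 lower of 10 (1 and 4 adjusted over the list alone; median -0.12, camera adjusted p = 4.99e-06). Dnmt1, Dnmt3a and Dnmt3b were 3 of the 4 lower members. The list kept that call with an estimated correlation (adjusted p = 0.043) and lost it with no filter on low counts (0.0681); without TKO day 2 replicate 2 there were 2 members lower and 0 higher, and the median was -0.01 without WT and -0.06 without TKO replicate 1. The list was also called lower at day 0 (1 higher and 2 lower, and 2 and 2 adjusted over the list alone; median 0.07, mean -0.52; 0.0247, and 0.244 with an estimated correlation), day 4 (2 and 2, and 2 and 3 alone; median 0.07, mean -0.18; 0.0263, and 0.259) and day 7 (2 and 4, also alone; median -0.25; 0.00878, and 0.182). The lower members were Dnmt1 and Dnmt3a at day 0 and Dnmt1 and Dnmt3b at day 4, and Dnmt1, Dnmt3a and Dnmt3b were among the 4 at day 7. The list holds the genes that TKO was assumed to lack, so its lower calls are no result separate from theirs. The day 0 call was also lost without WT replicate 2 (0.185), without TKO replicate 1 (0.0724) or 2 (0.100), with no filter on low counts (0.900), with a stricter filter (0.0699) and with only the libraries compared (0.198). The day 4 call was lost without TKO replicate 2 (0.356), with no filter on low counts (0.470) and with a stricter filter (0.0690), and the day 7 call with no filter on low counts (0.104).

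**Figure D2:**
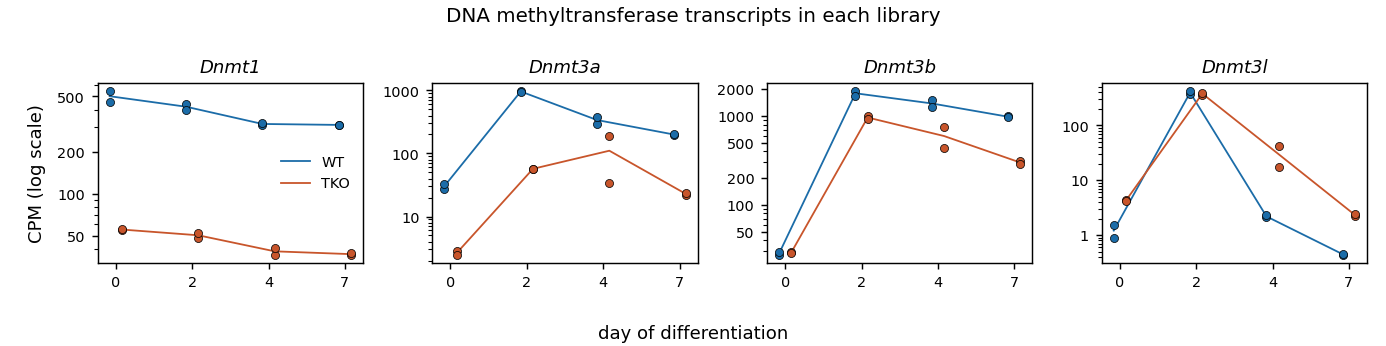
Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l in CPM (log y axis) against the day of differentiation; points are single libraries, colours the genotypes and lines join the means of 2 libraries. TKO day 4 replicate 1 reads 187 CPM of Dnmt3a and replicate 2 reads 33.9.

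The day 0 comparison asked how the genotypes differed in naive culture, before differentiation. A few genes of signalling through ERK, among others, were higher in TKO, while some germline and X-linked testis genes were lower and no gene of the naive pluripotency list was called. Egr1, an immediate-early gene induced by ERK, stood at 90.0 ± 1.90 CPM in TKO and 6.89 ± 0.229 in WT (log2 fold change 3.71 ± 0.32, adjusted p = 5.49e-05). Spry4, a feedback inhibitor of the same pathway, was up by 2.01 ± 0.14 and Etv4, an Ets factor downstream of FGF, by 1.30 ± 0.10. Of 12 FGF-ERK targets 3 rose and 1 fell, the same counts as adjusted over the list alone (median 0.15, camera adjusted p = 0.000306; adjusted p = 0.0685 with an estimated correlation). Other large rises were Krt42 (2.59 ± 0.18), Pramel7 (1.87 ± 0.31), Tbx15 (1.86 ± 0.15), Pramel6 (1.63 ± 0.19) and Kdr, the VEGF receptor of early mesoderm (1.51 ± 0.29). Lin28a, an RNA-binding protein that blocks let-7 maturation, rose by 1.04 ± 0.08 (adjusted p = 5.38e-06). It was 1 of 4 core pluripotency genes called higher of 10, with none lower (5 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 0.00147; adjusted p = 0.0685 with an estimated correlation). That count was 2 without WT replicate 1, and 2 without either TKO replicate.

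In the naive pluripotency list none of 21 genes was called at day 0 by edgeR, over all genes or adjusted over the list alone (0 and 0). Nanog was at 792 ± 0.365 CPM in TKO and 732 ± 7.87 in WT (0.11 ± 0.10, adjusted p = 0.528), and Pou5f1 at 872 ± 7.15 and 948 ± 206 (-0.12 ± 0.13, 0.582). Across all genes 5124 had an unadjusted p under 0.05 at day 0, and in DESeq2 2911 were called.

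Among germline genes 12 of 35 fell at day 0 and none rose (14 and 1 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 1.37e-06; adjusted p = 0.232 with an estimated correlation). Dmc1, the meiotic recombinase, fell by 3.07 ± 0.26, Dpep3 by 2.61 ± 0.31 (adjusted p = 0.000191) and Dazl, an RNA-binding protein of germ cells, by 1.07 ± 0.16, from 195 ± 7.37 CPM in WT to 93.3 ± 3.09 in TKO. X-linked Rhox, Xlr and Mage genes, whose promoters are usually methylated in somatic cells, had 6 lower and 0 higher of 20 (8 and 0 adjusted over the list alone; median -0.51, camera adjusted p = 9.67e-06; adjusted p = 0.232 with an estimated correlation). Xlr fell by 1.52 ± 0.24 and Xlr3c by 1.07 ± 0.16. Without TKO replicate 1 there were 6 germline and 3 X-linked members lower, and without TKO replicate 2 there were 6 germline members, with a germline median of -0.37. Rhox9 (1.26 ± 0.29, adjusted p = 0.0153) and Rhox6 (1.21 ± 0.29, 0.0172), listed with the primordial germ cell factors, were higher. The call of Rhox9 was lost without WT replicate 1 (0.0614) and without TKO replicate 1 (0.0722) or 2 (0.102). That of Rhox6 was lost without WT replicate 2 (0.0519), without TKO replicate 1 (0.0707) or 2 (0.117) and with only the libraries compared (0.0587). Further falls were Serpina3m (-4.98 ± 0.53), Gng2 (-3.27 ± 0.13), Fabp5 (-2.66 ± 0.17), Sfrp2 (-2.64 ± 0.18), Tspan2 (-2.61 ± 0.22) and Cmc1 (-2.59 ± 0.21).

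In all, 2343 genes were called at day 0, 835 higher and 1508 lower in TKO, 147 and 422 of them by 2-fold or more. This count depended on the fit, and was 359 when only the 4 libraries compared were fitted. The TKO libraries were close, with 6 genes at 5 CPM or more over 2-fold apart, and the WT libraries were not, with 116. The main fit shares the spread of a gene over all groups, so WT day 0 was not tested at its own wider spread. Leaving out 1 library leaves 1 in its group, so a lower count there need not mean reliance on that library.

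At day 2, as cells left the naive state, the comparison asked how far TKO cells followed WT cells. The Zscan4 cluster of the two-cell embryo was lower in TKO, 10 germline genes were lower and 2 higher, and a few neural genes were higher, but the list calls were lost with an estimated correlation. Of 18 two-cell-stage genes 11 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -3.63, or -2.73 with members at 0 counts set to their bound (camera adjusted p = 6.59e-13; adjusted p = 0.128 with an estimated correlation). Zscan4e stood at 0.387 ± 0.0832 CPM in TKO and 5.51 ± 0.175 in WT (-3.81 ± 0.62, adjusted p = 0.00329). The list count was 3 without WT replicate 2 and 1 without either TKO replicate. The summed level of the list was 3.60 ± 0.611 CPM in TKO and 36.8 ± 2.57 in WT, against 2.24 ± 0.630 and 2.81 ± 0.0383 at day 0.

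Of 35 germline genes 10 fell and 2 rose at day 2 (14 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 3.42e-05; adjusted p = 0.292 with an estimated correlation). Without WT replicate 2 there were 5 lower and without TKO replicate 2 there were 6, and leaving out any 1 of the 4 libraries left 1 higher. Tdrd1 of the piRNA pathway (-2.66 ± 0.31), Sycp3 of the synaptonemal complex (-2.20 ± 0.16, adjusted p = 3.06e-05) and the helicase Ddx4 (-1.11 ± 0.18) fell, while Asz1, a piRNA pathway gene on chromosome 6 (18050964 to 18109061), rose by 2.07 ± 0.17 (4.67e-05). Neural genes had 6 members higher and 1 lower of 21 (8 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 0.00631; adjusted p = 0.187 with an estimated correlation), and 3 higher and 0 lower without TKO replicate 2. Msi1, an RNA-binding protein of neural progenitors, was up by 0.51 ± 0.08. Other rises were B3gat1 (3.48 ± 0.35), Dyx1c1 (2.26 ± 0.30), Pde10a (2.16 ± 0.34), Med12l (2.07 ± 0.18), Wnk2 (1.98 ± 0.17) and the receptor Ret (1.83 ± 0.20).

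Formative and primed epiblast genes had 0 higher and 3 lower of 17 at day 2 (1 and 5 adjusted over the list alone; median -0.18, or -0.06 without TKO replicate 2; camera adjusted p = 0.152), and 0 lower without WT replicate 2 or either TKO replicate. Lef1 (-0.41 ± 0.09, adjusted p = 0.0108) and Pim2 (-0.36 ± 0.09, 0.0148) were lower; without WT replicate 2 and TKO replicates 1 and 2 the p were 0.102, 0.103 and 0.0554 for Lef1 and 0.139, 0.0967 and 0.0982 for Pim2. Fgf5 (-0.18 ± 0.21, adjusted p = 0.601), Otx2 (-0.21 ± 0.11, 0.206) and Pou3f1 (-0.31 ± 0.15, 0.172) were not called. Imprinted genes had 5 higher and 2 lower of 29, also adjusted over the list alone (camera adjusted p = 0.155), and 2 higher and 0 lower without WT replicate 2 or either TKO replicate. Nap1l5, on proximal chromosome 6, was up by 1.43 ± 0.15 and Ndn by 0.75 ± 0.12, while Snrpn (-0.43 ± 0.10, 0.0164) and Mcts2 (-0.35 ± 0.11, 0.0425) were lower. Without WT replicate 2 and TKO replicates 1 and 2 the p were 0.142, 0.0827 and 0.126 for Snrpn and 0.354, 0.122 and 0.247 for Mcts2, which was also not called with no filter on low counts (0.0580) or with an effective-length offset (0.0863).

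The cell-cycle inhibitor Cdkn1a rose by 0.58 ± 0.09 at day 2 (adjusted p = 0.00138); of 14 p53 targets it was the 1 called, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0421; adjusted p = 0.313 with an estimated correlation; 0.104 without WT replicate 1, 0.0914 without TKO replicate 1, 0.0703 with a stricter filter and 0.0517 with only the libraries compared). In all 2480 genes were called, 1460 higher and 1020 lower. The excess of higher genes rested on WT replicate 1, without which higher and lower genes were near equal in number. The count was 709 without WT replicate 2 (562 and 147), 986 without TKO replicate 1 (740 and 246) and 601 without TKO replicate 2 (481 and 120).

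At day 4 the question was whether TKO cells silenced germline and naive genes as WT cells did. Most measured genes of the germline list and of the X-linked Rhox, Xlr and Mage list were higher in TKO, as were many naive, neural and p53 target genes, whose list calls were lost with an estimated correlation. Asz1 stood at 25.8 ± 5.80 CPM in TKO and 0.0745 ± 0.0166 in WT (log2 fold change 8.36 ± 0.27, adjusted p = 1.76e-09). Mageb4 had 320 counts in TKO and 2 in WT, a ratio of 185 (95% counting interval 50.8 to 1535). Rhox2a, a homeobox gene of the X-linked Rhox cluster, was up by 5.77 ± 0.37, Tuba3b by 6.63 ± 0.40, Fkbp6, a chaperone of the piRNA pathway, by 3.51 ± 0.16 and Dazl by 1.98 ± 0.20. Of 35 germline genes 25 rose and 5 fell (25 and 5 adjusted over the list alone; median 1.95, camera adjusted p = 7.81e-23; 0.0383 with an estimated correlation). Sycp3 (-2.66 ± 0.15) and Dmc1 (-1.14 ± 0.18) were among those that fell. Of 20 X-linked members 19 rose and 0 fell, also adjusted over the list alone, with a median of 4.18, or 2.51 with members at their bound (camera adjusted p = 2.28e-20; 0.043 with an estimated correlation). The germline list summed to 531 ± 5.19 CPM in TKO and 268 ± 50.6 in WT.

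Naive pluripotency genes had 13 of 21 higher at day 4 and 0 lower, the same counts as adjusted over the list alone (median 0.89, camera adjusted p = 4.99e-06; adjusted p = 0.154 with an estimated correlation). Nr0b1, an orphan receptor of naive cells, was up by 3.38 ± 0.34, Esrrb by 1.89 ± 0.35, Fgf4 by 1.64 ± 0.14 and Zfp42 by 1.26 ± 0.22. Esrrb read 25.8 ± 16.3 CPM in TKO, where the libraries differed widely, and 7.02 ± 2.02 in WT. Pou5f1 (-0.05 ± 0.13, adjusted p = 0.817), Nanog (-0.18 ± 0.10, 0.233) and Fgf5 (0.02 ± 0.21, 0.955) were not called; Nanog was called lower without WT replicate 1 (-0.34, 0.0321). Neural genes had 13 higher and 1 lower of 21 (14 and 1 adjusted over the list alone; median 1.27, camera adjusted p = 6.8e-05; adjusted p = 0.0685 with an estimated correlation), among them Sox21 (4.00 ± 0.33), Sox1 (1.90 ± 0.15) and Pax6 (1.27 ± 0.23). Of 14 p53 targets 9 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.42, camera adjusted p = 9.76e-05; adjusted p = 0.0747 with an estimated correlation), among them Cdkn1a (1.35 ± 0.09, adjusted p = 4.15e-07) and Btg2 (0.92 ± 0.09). Without TKO replicate 1 the p53 median was 0.26.

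Some genes of several other lineages were higher at day 4, while primitive streak genes went both ways; the list calls were lost with an estimated correlation. Endoderm genes had 9 higher and 1 lower of 15 (12 and 1 adjusted over the list alone; median 1.59, camera adjusted p = 0.00465; adjusted p = 0.512 with an estimated correlation), with Gata6 (4.79 ± 0.60) and Sox17 (4.55 ± 0.61), regulators of endoderm fate. Trophoblast genes had 3 higher and 0 lower of 8 (4 and 0 adjusted over the list alone; median 0.72, camera adjusted p = 0.0286; adjusted p = 0.349 with an estimated correlation), including Gata2 (4.69 ± 0.44) and Plet1 (2.74 ± 0.20). Hox genes, which set position along the body axis, had 14 higher and 0 lower of 34 (15 and 0 adjusted over the list alone; median 1.83, or 1.97 with members at their bound; camera adjusted p = 0.0197; adjusted p = 0.729 with an estimated correlation), and 6 higher without WT or TKO replicate 1. Primordial germ cell factors had 6 higher and 1 lower of 11 (7 and 1 adjusted over the list alone; median 0.91, camera adjusted p = 0.0411; adjusted p = 0.195 with an estimated correlation). Without WT replicate 1 the camera p were 0.0936 for endoderm, 0.0584 for trophoblast, 0.148 for Hox genes and 0.0882 for primordial germ cell factors. Without TKO replicate 1, the library with high Dnmt3a, they were 0.0684, 0.0899, 0.379 and 0.119, and the medians of endoderm, trophoblast and Hox genes were 0.88, -0.07 and 0.45; that of trophoblast was 1.19 without TKO replicate 2. With no filter on low counts that of trophoblast genes was 0.0988, and that of primordial germ cell factors was 0.0643 with a stricter filter and 0.0746 with only the libraries compared. Interferon response genes had 9 higher and 2 lower of 17 (10 and 2 adjusted over the list alone; median 1.01, camera adjusted p = 0.00993; adjusted p = 0.117 with an estimated correlation), with Isg15 (3.83 ± 0.50) and Rsad2 (2.60 ± 0.26) up. Without TKO replicate 2 there were 5 higher and 1 lower, and without WT replicate 1 there were 6 and 1.

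Primitive streak and mesoderm genes had 4 higher and 2 lower of 15, also adjusted over the list alone (median -0.33, mean 0.99, camera direction up, adjusted p = 0.572). The counts were 4 and 4 without WT replicate 1, 5 and 0 without WT replicate 2, 3 and 3 without TKO replicate 1 and 5 and 1 without TKO replicate 2, and the median was -0.12, 0.41 and 0.18 without WT replicate 1, WT replicate 2 and TKO replicate 2. The streak genes Eomes (-1.22 ± 0.36, adjusted p = 0.0269) and Fgf8 (-1.62 ± 0.42, 0.0139) fell. The call of Eomes was lost without WT replicate 2 (0.246), without TKO replicate 2 (0.154), with no filter on low counts (0.0813) and with only the libraries compared (0.146). That of Fgf8 was lost without WT replicate 2 (0.0876), without TKO replicate 1 (0.0916) and with only the libraries compared (0.0945).

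Falls at day 4 were fewer among large changes: 1937 genes were higher and 262 lower by 2-fold or more. Snph (-2.61 ± 0.17), Pla2r1 (-2.73 ± 0.41), Mcoln3 (-2.52 ± 0.29), Fbp1 (-2.35 ± 0.24) and Zfhx4 (-2.35 ± 0.29) fell, as did Nkx1-2, a factor of the caudal epiblast (-2.09 ± 0.30), Lin28a (-0.73 ± 0.08) and the kinase Pim2 (-1.19 ± 0.09). In all 5342 genes were called, 3296 higher and 2046 lower. The count was 4200 without TKO replicate 1 and 2822 when only the 4 libraries compared were fitted.

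Day 7 asked for the end state. In TKO, germline genes, X-linked testis genes, the Zscan4 cluster and genes of the primitive streak were high, and Hesx1, Otx2, Sox2 and some imprinted genes were low; the list calls of the Zscan4 cluster and of the primitive streak were lost with an estimated correlation. Asz1 stood at 50.2 ± 0.796 CPM in TKO and at 0 counts in WT, at least 1388-fold higher (3 counts over the group as the floor). Dazl had 1687 counts against 1, a ratio of 1967 (353 to 77751), and Mael, a piRNA pathway gene, 138 against 1 (161, 28.4 to 6402). Ddx4 was up by 6.84 ± 0.29 (adjusted p = 1.67e-09) and Fkbp6 by 6.72 ± 0.24. Of 35 germline genes 28 rose and 2 fell (28 and 3 adjusted over the list alone; median 6.28, camera adjusted p = 1.92e-43; 0.00884 with an estimated correlation). Dmc1 (-1.22 ± 0.25) and Gtsf1l (-1.32 ± 0.36) were the 2 that fell. The list summed to 637 ± 4.07 CPM in TKO and 101 ± 1.85 in WT. X-linked Rhox, Xlr and Mage genes had 18 higher and 1 lower of 20 (19 and 1 adjusted over the list alone; median 5.20, or 4.11 with members at their bound; camera adjusted p = 1.08e-22; 0.0368 with an estimated correlation). Mageb4 was at least 755-fold and Pramel3 at least 1322-fold higher, and Xlr4c rose by 4.05 ± 0.17.

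All 18 measured two-cell-stage genes rose at day 7, also adjusted over the list alone, with a median of 10.76, or 8.87 with members at their bound (camera adjusted p = 4.74e-15; adjusted p = 0.115 with an estimated correlation). Zscan4f was at least 3801-fold higher, Zscan4c at least 2082-fold and Zscan4d at least 1332-fold, and Tmem92 had 12293 counts against 3, a ratio of 4779 (1635 to 23175). The list summed to 743 ± 287 CPM in TKO and 1.41 ± 0.0843 in WT, so its level varied widely between the TKO replicates. Fitted on only the 4 libraries compared, Zscan4f (adjusted p = 0.0997), Zscan4c (0.0959) and Zscan4d (0.108) were not called.

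Primitive streak and mesoderm genes had 12 higher and 0 lower of 15, the same counts as adjusted over the list alone (median 1.66, camera adjusted p = 1.98e-06; adjusted p = 0.182 with an estimated correlation). T, the founding factor of mesoderm, was at 521 ± 7.66 CPM in TKO and 47.3 ± 6.09 in WT (3.46 ± 0.60, adjusted p = 0.00119). Mixl1 was at 80.3 ± 7.35 and 6.86 ± 0.977 (3.55 ± 0.22), Tbx6, of presomitic mesoderm, was up by 4.27 ± 0.31 and Pdgfra, on the endoderm list but also a receptor of early mesoderm, by 3.02 ± 0.32. Nodal rose by 0.90 ± 0.23 and Lef1, a mediator of Wnt signalling, by 1.24 ± 0.09. Beta protocadherins, neuronal adhesion genes in a cluster under methylation control, had 9 higher and 0 lower of 13 (10 and 0 adjusted over the list alone; median 1.75, camera adjusted p = 0.0166; adjusted p = 0.293 with an estimated correlation). That call was lost with only the libraries compared (0.0746), and 4 were higher without WT replicate 2 and 5 without TKO replicate 2. Of 14 p53 targets 12 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.0145; adjusted p = 0.232 with an estimated correlation), including Cdkn1a (0.97 ± 0.09) and Ccng1 (0.60 ± 0.08).

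Single developmental genes fell at day 7. Hesx1, a repressor of the anterior neural plate, changed by -6.69 ± 0.53 (adjusted p = 4.17e-07), Sfrp5, a secreted Wnt inhibitor, by -8.30 ± 0.37 (2.49e-09), and Sox2 by -1.81 ± 0.21. Otx2, a regulator of head development, fell from 197 ± 29.7 CPM in WT to 98.0 ± 0.868 in TKO (5.69e-06). Sox2 was at 16.1 ± 1.05 CPM in TKO and 56.5 ± 3.66 in WT, while Nanog did not differ detectably (0.09 ± 0.11, adjusted p = 0.515). Utf1 (-1.62 ± 0.15), Msi1 (-1.23 ± 0.08), Lin28a (-1.17 ± 0.08) and Pou3f1 (-0.76 ± 0.16) fell as well. The definitive endoderm factor Sox17, which was higher at day 4, fell by 2.89 ± 0.31. Imprinted genes moved in both directions, 10 higher and 12 lower of 29, also adjusted over the list alone (fry mixed adjusted p = 4.79e-11; camera 0.239). Of all tested genes 44.5% were called at day 7. The mixed fry adjusted p was 0.0341 or lower for every list, so it does not set imprinted genes apart. Grb10, a growth inhibitor, was at 7.48 ± 0.364 CPM in TKO and 205 ± 32.8 in WT (-4.77 ± 0.17, adjusted p = 3.95e-10), and Dio3 fell by 2.64 ± 0.27, while Cdkn1c rose by 5.32 ± 0.30 and Ndn by 0.86 ± 0.11. Myl3 (-6.29 ± 0.44), Clic6 (-4.63 ± 0.23), Tuba8 (-4.50 ± 0.35) and Vwf (-4.14 ± 0.19) were further large falls. In all 8227 genes were called, 4324 higher and 3903 lower, with 1752 higher and 271 lower by 4-fold or more.

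**Figure D3:**
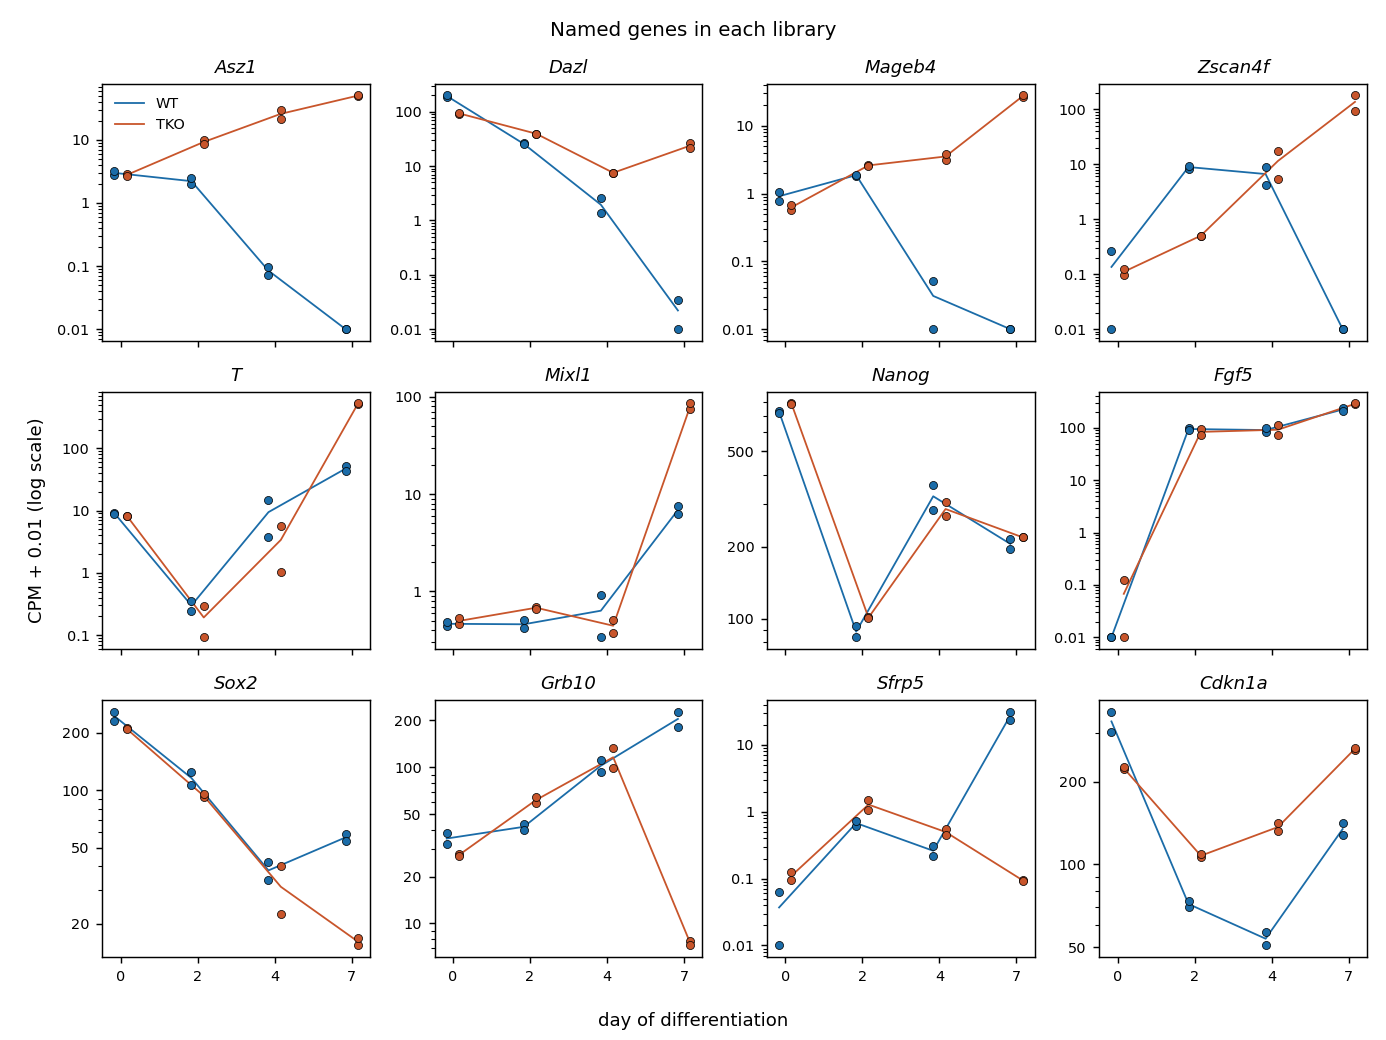
Levels of 12 named genes in CPM plus 0.01 (log y axis) against the day of differentiation; points are single libraries and colours the genotypes. At day 7 Asz1 reads 50.2 ± 0.796 CPM in TKO and 0 counts in WT, T reads 521 ± 7.66 and 47.3 ± 6.09, and Grb10 reads 7.48 ± 0.364 and 205 ± 32.8.

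Within WT cells, day 7 against day 0 gave the course of normal differentiation. Naive pluripotency genes were all lower, 21 of 21, also adjusted over the list alone (median -6.98, camera adjusted p = 8.31e-32; 0.00779 with an estimated correlation). Formative and primed epiblast genes had 16 higher and 1 lower of 17, also adjusted over the list alone (median 2.60, camera adjusted p = 9.29e-21; 0.00779 with an estimated correlation). Fgf5, the marker of the postimplantation epiblast, was at least 5758-fold higher, Otx2 rose by 3.96 ± 0.12 and Dnmt3b by 5.11 ± 0.22, while Klf4 (-6.80 ± 0.20), Esrrb (-8.09 ± 0.44) and Zfp42 (-9.17 ± 0.32) fell and Pou5f1 did not change detectably (-0.24 ± 0.13, adjusted p = 0.104). Germline genes had 28 lower and 4 higher of 35, also adjusted over the list alone (median -5.82, or -5.60 with members at their bound; camera adjusted p = 1.03e-14; adjusted p = 0.0747 with an estimated correlation), and 2 higher without WT day 0 replicate 1. Dazl went from 15006 counts to 1, a ratio of 16196 (2907 to 639770), and Rpl10l and Sohlh2 were at least 4256-fold and 1627-fold lower. X-linked Rhox, Xlr and Mage genes had 19 lower and 0 higher of 20, also adjusted over the list alone (median -7.84, or -4.61 with members at their bound; camera adjusted p = 8.32e-13; adjusted p = 0.0756 with an estimated correlation). Nodal-Activin targets had 5 higher and 0 lower of 7, also adjusted over the list alone (median 1.82, camera adjusted p = 0.031; adjusted p = 0.591 with an estimated correlation; 0.0627 and 0.0764 without WT day 0 replicate 1 and 2, and 0.0662 with a stricter filter). Cer1 (15074 counts against 2, a ratio of 6983, 1933 to 57666), Lhx1 (5444, 1507 to 44959) and Pcdh7 (at least 1433-fold) were among the largest rises. In all 12233 genes were called, 6089 higher and 6144 lower; 11372 were called at day 2 and 11678 at day 4.

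Within TKO cells the exit from the naive state was of similar breadth: 21 of 21 naive genes were lower (median -6.25, camera adjusted p = 1.87e-30; 0.00779 with an estimated correlation) and 17 of 17 formative genes higher (median 3.38, 4.36e-20; 0.00779), the same counts as adjusted over the list alone. Fgf5 rose by 12.22 ± 0.44 and Otx2 by 3.14 ± 0.12, and Klf4 (-4.75 ± 0.18), Zfp42 (-7.44 ± 0.28), Nanog (-1.86 ± 0.11) and Sox2 (-3.70 ± 0.22) fell. Germline genes did not fall as a group: 20 were higher and 10 lower of 35, also adjusted over the list alone (median 0.84, camera adjusted p = 0.515). Asz1 rose by 4.18 ± 0.18 and Ddx4 by 2.06 ± 0.19, while Dazl fell by 1.97 ± 0.16 and Fkbp6 by 2.45 ± 0.13. T (5.97 ± 0.70), Mixl1 (7.36 ± 0.30), the neuropeptide gene Trh (4.98 ± 0.35) and the cadherin Cdh2 (7.41 ± 0.16) rose, and Prdm14, a repressor of naive cells' exit, went from 3994 counts to 1 (a ratio of 4069, 730 to 160750). In all 12541 genes were called at day 7, 6679 higher and 5862 lower, and 10546 and 11653 at days 2 and 4.

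The interaction asked directly whether the genotype difference changed from day 0. It was called for 1399 genes at day 2 (1065 positive, 334 negative), 3012 at day 4 (2150 and 862) and 5014 at day 7 (2930 and 2084). Of 35 germline genes 24 had a positive and 1 a negative interaction at day 4, and 28 and 0 at day 7; of the 20 X-linked genes 19 and 0 on both days. The germline genes Dazl (3.04, adjusted p = 4.67e-06) and Asz1 (8.47, 3.59e-08) at day 4 and Ddx4 (7.02, 1.94e-08) at day 7 gave large positive values, as did T at day 7 (3.60, 0.0124). Negative ones included Hesx1 (-7.02, 3.56e-06), Grb10 (-4.42, 1.73e-08) and Sox2 (-1.59, 0.0012) at day 7. The day 2 count was 624 without TKO day 0 replicate 1, 627 without TKO day 0 replicate 2, 758 without TKO day 2 replicate 1, 684 without TKO day 2 replicate 2, 855 without WT day 2 replicate 2 and 2241 without WT day 0 replicate 1. The day 4 count was 1875 and 1918 without TKO day 0 replicate 1 and 2. The split by direction rested on both WT day 0 replicates. On each later day the share of positive ones was smaller without replicate 1, and also without replicate 2, than in the main fit. At day 2 it was smallest without replicate 1, and at days 4 and 7 without replicate 2. Without replicate 2 negative ones were the more numerous at day 7.

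Part of chromosome 6 was shifted. The chromosome had a median log2 fold change above all 10000 expression-matched sets on each day (0.06, 0.12, 0.30 and 0.22; 0.10 at day 0 without WT replicate 2). Other chromosomes lay beyond all sets on single days. At day 0 chromosomes X (-0.13), 14 (-0.11) and 3 (-0.08) lay below them, each further from 0 than chromosome 6, and chromosome 11 (0.02) above; chromosome 17 lay below them at day 4 (-0.05) and day 7 (-0.09), and Y above them at day 7 (3.74). Without WT day 0 replicate 2 the medians were -0.05 for chromosomes 14 and 3 and 0.01 for 11, and 11 had 0.05 without WT and 0.03 without TKO day 0 replicate 1. Chromosome 17 had -0.03 at day 4 without WT replicate 1 and -0.13 at day 7 without TKO replicate 2. A single change point along the chromosome, found by scan on the mean of the 4 days, lay at 81.9 Mb, with medians of 0.34 before and 0.00 after it; single days gave 82.0, 73.0, 83.1 and 72.6 Mb. The 404 tested genes before it had medians of 0.19, 0.23, 0.53 and 0.51 on days 0, 2, 4 and 7. Asz1, Nap1l5 and other genes named above lie there. How far the regional shift contributes to their fold changes was not tested, and no list test was repeated without the genes of the region. Leaving the 404 genes out, 2282, 2389, 5129 and 8004 genes were called on the 4 days.

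**Figure D4:**
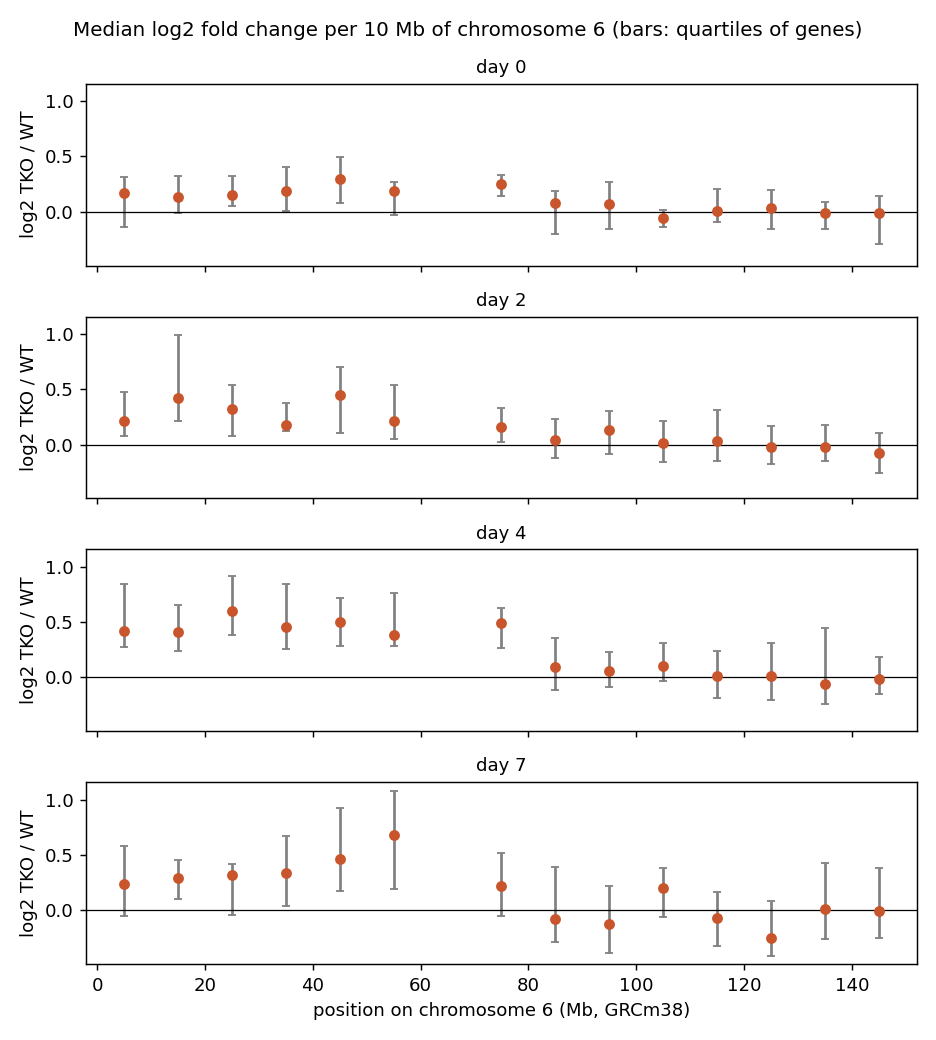
Median log2 fold change of TKO against WT for genes with at least 5 CPM in bins of 10 Mb along chromosome 6 (x axis, Mb), with quartiles as bars, for each day; the region before 81.9 Mb has medians of 0.19, 0.23, 0.53 and 0.51 on days 0, 2, 4 and 7 over all 404 tested genes.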

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

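No test reported in this part was chosen after its result was seen, and no explanation is weighed here. The values below are interactions, log2 differences between the TKO against WT difference of a later day and that of day 0, each past an adjusted p of 0.05 in edgeR. They were singled out because the genotype difference itself changed between days. There were 1399 such genes at day 2, 3012 at day 4 and 5014 at day 7. Among the genes named by the fixed rule 51 interactions were called; 12 are left out because a group held 3 counts or fewer, and 38 of the other 39 follow.

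At day 2 the positive ones were Tlx2, a homeobox gene of the neural crest (3.81), Tspan2 (3.72), the protease Prss50 of meiotic cells (3.35), the adhesion receptor Adgrg6 (3.21), Gng2 (3.00) and Dazl (1.69). Gng2, Tspan2 and Dazl were lower in TKO at day 0. The negative ones were Ddx4 (-0.93), Sycp3 (-1.36), Pramel6 (-2.58) and Pramel7 (-2.82), and Srp54b (-8.03). The call of Prss50 was lost without TKO day 0 replicate 1 (adjusted p = 0.0575) or 2 (0.0561). That of Srp54b was lost without TKO day 0 replicate 2 (0.0671) or TKO day 2 replicate 1 (0.0556). That of Pramel6 was lost without WT day 2 replicate 2 (0.196) or TKO day 2 replicate 1 (0.0551) or 2 (0.0786), that of Pramel7 without WT day 2 replicate 2 (0.0501), and that of Ddx4 without any 1 of the 8 libraries (0.0771 to 0.161). With an effective-length offset Srp54b (0.0808), Pramel7 (0.0960) and Ddx4 (0.0824) lost theirs as well.

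At day 4 the positive ones were Asz1 (8.47), Tktl2 (8.03), Tuba3b (7.58), Sox17 (4.74), Dppa3, a maternal factor of germ cells and naive cells (3.16), Dazl (3.04), Sox1 (1.89), Esrrb (1.74), Zfp42 (1.10), Prdm1, a repressor that specifies germ cells (0.98), and Klf4 (0.80). The negative ones were Sycp3 (-1.82), Prr5l (-2.46), the Wnt antagonist Rnf43 (-2.58), the glutamate receptor gene Grin1 (-2.80), Fgd2 (-2.95) and Pnpla3 (-3.49). Dppa3 lost its call without TKO day 4 replicate 1 (adjusted p = 0.0887). Prdm1 lost its call without any 1 of 7 libraries, WT day 4 replicate 2 being the exception (0.0644 to 0.162). Klf4 lost its call without WT day 0 replicate 1 (0.0541) or 2 (0.0548), WT day 4 replicate 2 (0.123), TKO day 0 replicate 1 (0.102) or 2 (0.0994), or TKO day 4 replicate 2 (0.134). Esrrb lost its call without WT day 0 replicate 1 (0.0737) or 2 (0.0717), WT day 4 replicate 1 (0.0933), or TKO day 0 replicate 1 (0.0810) or 2 (0.0799). Zfp42 lost its call without WT day 0 replicate 1 (0.0850), WT day 4 replicate 1 (0.0920), TKO day 0 replicate 1 (0.0781) or 2 (0.0756), or TKO day 4 replicate 1 (0.0651). With no filter on low counts Esrrb (0.0858), Zfp42 (0.0946), Klf4 (0.0560) and Prdm1 (0.0705) lost theirs, as they did with only the libraries compared (0.0964, 0.0844, 0.0893 and 0.138), and with an effective-length offset Klf4 (0.139) and Prdm1 (0.107) did.

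At day 7 the positive ones were Ddx4 (7.02), T (3.60), Klf4 (2.05) and Zfp42 (1.73). The negative ones were Otx2 (-0.82), Sox2 (-1.59), Sox17 (-2.70), Grb10 (-4.42), the pepsinogen gene Pga5 (-5.04) and Hesx1 (-7.02). Zfp42 lost its call without WT day 7 replicate 2 (adjusted p = 0.0580), and Pga5 without WT day 0 replicate 1 (0.0639) or 2 (0.0714) or TKO day 0 replicate 2 (0.0764), and with no filter on low counts (0.0518).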

How the results depend on the processing

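The tests without proximal chromosome 6, with a crossed replicate block, and with a replicate block on only the libraries compared were chosen after the results were seen. With RLE scaling, a stricter filter on low counts or none, and DESeq2, every count of called genes stayed within 1.5 times its main value. At the stricter threshold of 0.01 the TKO against WT counts were 923 at day 0, 929 at day 2 and 3111 at day 4, and the interactions 517, 1547 and 3052 on days 2, 4 and 7, a stricter threshold calling fewer by construction. With an effective-length offset day 2 gave 1602 and its interaction 863, and Dnmt3a at day 0 was -3.05 (adjusted p = 0.0529); the cause was not tested. With only the libraries compared, day 0 gave 359, day 4 gave 2822 and the day 4 interaction 1548, while day 2 rose to 3505 and day 7 to 10495; the cause was not tested.

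The replicate numbers do not mark a pairing shared by all groups: of 28 pairs of groups 1 had replicate differences correlated above 0.1 (highest 0.105) and 3 below -0.1. The lowest was -0.556, between WT day 0 and WT day 2, so a factor shared in crossed order is not excluded for these groups. With a replicate block, counts were 1992, 2098, 4972 and 7880 on the 4 days, and no count moved by over 1.5 times; 12 of 703 named-gene results lost their call, among them the interactions of Ddx4 at day 2 (adjusted p = 0.0681) and Prdm1 at day 4 (0.0603). On only the libraries compared, WT day 2 against day 0 gave 8885 calls without a block and 7414 with a replicate block. With a crossed replicate block, in which the numbers of 1 group were swapped, it gave 12023. TKO against WT at day 4 gave 2822 without a block, 1168 with a replicate block and 3017 with a crossed one.

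Leaving out 1 library gave 697 to 4322 calls at day 0, 601 to 2050 at day 2, 624 to 2241 for the day 2 interaction and 1875 to 4313 for the day 4 interaction. Dnmt3a ranged from -3.65 to -3.37 at day 0 and from -3.33 to -0.86 at day 4. Dnmt3b ranged from -0.97 to -0.82 at day 2 and from -1.68 to -0.87 at day 4. Dnmt3a at day 4, not called in the main fit, was called with a stricter filter (-1.60, adjusted p = 0.0301), in DESeq2 (-1.60, 0.0244) and without either TKO day 4 replicate. The day 4 interaction of Tfap2c reversed, from -0.81 without TKO day 4 replicate 1 to 0.72 without replicate 2; the cause was not tested.

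Of 120 list tests 49 were called with the preset correlation and 10 with an estimated one. The DNA methylation machinery list reversed at day 0 with no filter on low counts (adjusted p = 0.900), where more genes form the background; the cause was not tested. Chromosome medians with a stricter filter were 0.0824 for chromosome 6 at day 0, -0.00559 for chromosome 8 at day 2 and 0.00795 for chromosome 7 at day 4. Without 1 library they ranged as follows: chromosome 2 at day 0, -0.00922 to 0.0277; chromosome 6, 0.0593 to 0.0991 at day 0, 0.105 to 0.140 at day 2, 0.211 (without TKO replicate 1) to 0.346 (without TKO replicate 2) at day 4 and 0.195 to 0.213 at day 7; chromosome 7 at day 4, -0.0187 to 0.0297; chromosome 8 at day 2, -0.0116 to 0.0290; chromosome 18 at day 7, -0.000260 to 0.0405. Depth limits genes near 0 counts in WT at day 7, for which the text gives bounds.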

Other observations

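The 3 tests on chromosome 6, on genes left out of the scan that found the region, and both tests of a WT share on genes other than Dnmt3a, were chosen after the result was seen. The summed level of the two-cell-stage list in WT was 2.81, 36.8, 30.2 and 1.41 CPM on days 0, 2, 4 and 7, and in TKO 2.24, 3.60, 52.8 and 743. Against day 0, 14 of its 18 members were higher in WT at day 2 (9 without WT day 0 replicate 1) and 0 in TKO. At day 4 it was 13 in WT and 17 in TKO, and TKO against WT called 3 higher (7 without TKO day 4 replicate 2). At day 7 it was 18 in TKO (camera adjusted p = 0.000161; 0.441 with an estimated correlation). The TKO level varied between libraries, with an SD of 31.5 at day 4 and 287 at day 7.

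Several lists held members moving both ways at day 7. Naive genes had 9 higher and 4 lower in TKO (median 0.64, or 0.25 without TKO day 7 replicate 1; camera adjusted p = 0.177), with Klf4 up (1.99 ± 0.20) and Spp1 down (-3.48 ± 0.34). Neural genes had 6 higher and 7 lower, and 4 lower without WT day 7 replicate 1 (median 0.09, or -0.01 without WT day 7 replicate 2; camera direction down, 0.773), with the neuronal genes Dcx (3.72 ± 0.26) and Neurod1 (2.16 ± 0.23) up and Irx3 (-2.14 ± 0.29) down. Primordial germ cell factors had 5 higher and 2 lower (median 1.39, or 0.48 without TKO day 7 replicate 1; 0.113), with Dnd1 (3.81 ± 0.27) and Nanos1 (2.87 ± 0.18) up and Prdm1 (-0.88 ± 0.21) down. The feeder and stromal fibroblast list had 2 higher and 1 lower of 8 (median -0.39, or 0.00 without WT day 7 replicate 1, mean 0.09, camera direction up, 0.681), with Pdgfrb (2.48 ± 0.17) and Dcn (2.78 ± 0.65) up. The summed level of that list went the other way, at 89.1 ± 3.40 CPM in TKO and 226.5 ± 10.2 in WT. On the Y chromosome the median over 27 genes at day 7 was 3.74 (15 higher, 2 lower), above the highest of 10000 matched sets (2.36).

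Genes of proximal chromosome 6 were higher in TKO on each day. A scan of every other gene of the 19 autosomes for a single change point removed most deviation on chromosome 6 (16.4%, at 81.9 Mb; at most 3.42% on the others), and the proximal genes left out of that scan were then tested, 202 against matched sets and the 108 of them with at least 5 CPM for shifts per library. GC content, length and expression are argued against, since their median exceeded the highest of 10000 matched sets by at least 0.120. A scaling difference moves all genes of a library alike, so it cancels from a shift against the other autosomes. That shift was at least 0.244 in each TKO library. The region was chosen because it stood apart from other genes, so this outcome was to be foreseen and is no separate support. The same copy gain in all TKO cells on all days is argued against as the only source of the shift, since the lowest day 4 shift was 0.201 above the highest day 0 shift. This takes a constant gain to give the same log2 shift on each day. A constant gain with further expression differences on later days stays open. The shifts were 0.252 and 0.244 at day 0, 0.275 and 0.279 at day 2, 0.587 and 0.453 at day 4 and 0.418 and 0.341 at day 7, so they did not keep growing. A gain in a share of the cells that differed between days may explain the pattern; it was not tested, and a regional effect of genotype also stays open.

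TKO day 4 replicate 1 stood apart. Genes rising between TKO day 2 and day 7 differed by a median of 0.0209 between the replicates (1031 genes, matched range -0.0205 to 0.0287). The prediction for a shift in stage, rising and falling genes moved in opposite directions and both outside their ranges, was therefore not met. The rising genes were chosen on days 2 and 7 alone, and those that rise only after day 4 would show no difference. The test thus does not decide on a shift in stage. The 585 falling genes were higher in replicate 1 by 0.195, outside their range (-0.0336 to 0.0262), so a difference in timing is not excluded. The level of Dnmt3a would need 50.3% of WT cells or RNA in the library. A share of that size is argued against: other genes at least 8-fold lower in TKO replicate 2 than in WT implied a median of -0.0455% (4 genes), and those at least 4-fold lower -0.151% (8 genes), both with an upper quartile of 8.40%. Dnmt1 implied -1.63% and Dnmt3b -52.2%. Of these genes Wnt8a (33.4%) and the pseudogene Rpl14-ps1 (55.6%), chosen after their values were seen, did go with such a share, and a smaller share stays open. What raised Dnmt3a in this library stays open. No biological explanation was tested.

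Of 35 germline genes 12 were lower and none higher in TKO at day 0 (edgeR), and the camera call was lost with an estimated correlation (adjusted p = 0.232). GC content, length and expression level are argued against for the list's shift, since the list median of -0.56 lay at percentile 0.01 of 10000 matched sets (central 95%, -0.32 to 0.02). Without TKO day 0 replicate 2 the median was -0.37, nearer to that range; no matched sets were drawn for it. A single library is argued against as the only source. Without each of the 4 libraries in turn the list median stayed between -0.59 and -0.37. The fewest lower members called without 1 of the 4 libraries was 6 of 12, which only just met the bound set beforehand. The 2 TKO libraries were close to each other, so this test does not reach a trait that both share. An effect of genotype in naive culture may explain the lower germline genes, which these data cannot separate from differences between the cultures of the cell lines.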
